A study of Mus musculus with 12 samples.

How the data were processed

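The samples were mouse embryonic stem cells of strain C57BL/6, per the labels, that were wild type or knockout (KO) for Prdm5 and were either deprived of LIF or differentiated with all-trans retinoic acid (ATRA). Each of the 4 groups had 3 RNA-seq libraries, 12 in all. The labels describe RNA extraction with RNeasy Plus columns and cDNA synthesis for qRT-PCR, and the library preparation is not given in the sources used here.

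Per the submitters' processing notes, the authors checked the reads with FastQC, aligned them with TopHat to mouse genome build mm9 and estimated expression with Cufflinks; versions, settings and the gene annotation are not given in the sources used here. The deposited table holds FPKM values computed by the authors, 1 per gene and group, with a lower and an upper confidence bound and a status, in the layout of a Cufflinks gene tracking table exported through cummeRbund. It holds no value per library, no read counts and no test results. The analysis designed before the data were examined assumed 1 value per library and a linear model across the 12 samples, so the file held another form than the design assumed. The design's own fallback for this case was used, a description of the authors' table without a test. No depth per library can be given, because no counts are in the table; the bounds are the only measure of precision. For genes at 50 to 200 FPKM the median distance from a group value to its bound was 19.0%, 13.5%, 15.0% and 15.1% of the value (wild type and KO under LIF deprivation, wild type and KO under ATRA), and at 1 to 5 FPKM it was 28.9%, 24.2%, 32.2% and 32.9%.

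The table has 23768 entries, of which 1333 carry no gene name and 393 carry several symbols because overlapping genes were merged into 1 locus. Named entries with an FPKM of at least 1 in at least 1 group (12079) were kept. In each comparison a gene was tested when both groups had status OK, an FPKM above 0 and bounds of non-zero width. Status FAIL was given to 752, 310, 192 and 170 entries in the groups in the order above, and status HIDATA to 6 in each; these values were not used. Genes listed at 0 in a group have no fold. FPKM sums were 744031, 796913, 668565 and 714631, and ribosomal protein genes held 27.3%, 30.5%, 24.8% and 24.3% of them.

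Differences are of log2(FPKM + 1). Their intervals combine the distances of both groups to their bounds on that scale, by the square-and-add (MOVER) method. A gene is called separated when the bounds of the groups do not overlap. The bounds are those that Cufflinks documents as 95% limits, which the file itself does not state, and how far they reflect variation between replicates is not known, so separation is not a replicate-based test. This criterion was chosen after the layout of the file was seen and stands in for a significance call. The number expected by chance was computed from the widths of the intervals, taking them as 95% limits of normal errors. The interaction is the KO minus wild-type difference under ATRA minus that under LIF deprivation, separated when the intervals of the 2 differences do not overlap.

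There were 5 comparisons: KO against wild type under LIF deprivation and under ATRA, ATRA against LIF deprivation in wild-type and in KO cells, and the interaction. In each comparison the text names Prdm5, up to 10 separated genes with the largest increase and up to 10 with the largest decrease, and up to 4 separated members of each gene list or, where none separated, up to 2 with the highest mean. For the interaction it names the 10 most clearly separated genes. Genes with only a clone or predicted name and small RNAs were counted but not named. Other genes that the text names were chosen after their values were seen.

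Gene lists were written down from general knowledge before the file was opened: naive pluripotency, primed pluripotency, retinoic acid response, Hox genes, neural progenitor, neuron, extraembryonic endoderm, mesoderm and primitive streak, trophoblast, 2-cell-like, imprinted genes, insulator with cohesin and TFIIIC, clustered protocadherins, collagens and matrix, fibroblast (feeder), endothelial and blood, cardiac and smooth muscle, Prdm family, Wnt targets, p53 targets, cell cycle, replication-dependent histones, immediate early and heat shock, ATF4 and unfolded protein response, hypoxia and glycolysis, interferon response, germline, ribosomal proteins, mitochondrial genes and sex chromosome markers. Of 471 symbols given in full, 461 were found by symbol, 4 by a synonym and 6 not at all. The ribosomal list leaves out kinases, Rps19bp1 and pseudogenes. Few genes are on more than 1 list, among them Acta2, Cdx1, Cdx2, Kdr, Prdm14, Ascl2, T and 5 collagen and matrix genes on the fibroblast list. For each list of at least 3 tested members, the median difference was ranked among 10000 random lists of genes drawn from the same 20 bins of expression, and percentiles under 2.5 or over 97.5 are called outside the random range. These percentiles describe genes and are not tests over replicates. Of 140 medians ranked, 64 lay outside the range, against 7 expected by chance if the members of a list varied independently. Members of 1 list can vary together, as near-identical copies such as those of Zscan4 do, and the ranks then overstate how rare a median is.

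Transcript length and GC content were those of the longest annotated transcript of each symbol in GENCODE M21, available for 96.7% of the genes tested under LIF deprivation. Trends of the log2 FPKM ratio on length, on GC content or on both in turn were removed with a lowess fit (fraction 0.3). As a control for the centring that this brings, length and GC content were shuffled together among genes in 20 runs and removed in the same way. Positions are locus extents in mm9 as in the file. Around Prdm5 the share of separated genes within 5 Mb and within 20 Mb was given as a percentile among windows of the same width around other autosomal genes. Those windows held at least 10 genes, and the window of 5 Mb around Prdm5 held only 6. Windows near Prdm5 were not left out, and they count Prdm5 itself, which its own window does not. The alternatives were a pseudocount of 0.1, no expression filter, a minimum FPKM of 5, median-ratio scaling and quantile normalization of the groups, the removal of each trend, a looser criterion (the interval of the difference leaves out 0), a ratio of at least 1.5, and the larger window. Alternatives that need values per library were not run.

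The procedure was tested on simulated data with known changes in 200 genes per comparison. The simulated errors were normal and had the size that the deposited bounds imply, and variation between replicates was not simulated. The shares recovered therefore hold only if the bounds are right, which is not known, and they are no check on the bounds themselves. In the KO comparisons under LIF deprivation and ATRA, of 50 genes per size and direction, 78% and 62% were recovered at a change of 1 on the log2 scale, 88% and 84% at -1, and 54% and 38% at 0.5, and none was called in the wrong direction. In KO cells between ATRA and LIF deprivation the shares were 82% at 1 and 76% at -1, and differences between directions were not tested. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.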

Results

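Mouse embryonic stem (ES) cells that were wild type or knockout (KO) for Prdm5, a PR-domain zinc-finger protein, were compared in 2 conditions. In one the cells were deprived of LIF, the cytokine that keeps mouse ES cells undifferentiated, and in the other they were differentiated with all-trans retinoic acid (ATRA). Each of the 4 groups had 3 RNA-seq libraries, but the deposited table holds 1 FPKM per gene and group, with a lower and an upper confidence bound. No spread between replicates can therefore be given, and no difference was tested against replicates. Genes whose bounds did not overlap between groups are called separated, and words such as higher, lower, rose and fell are used of single genes only when they were separated. Differences are in log2(FPKM + 1), each with the interval that the bounds give.

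Prdm5 transcript was nearly lost in the KO cells in both conditions. Under LIF deprivation its level was 7.74 FPKM in wild-type cells (bounds 6.03 to 9.45) and 0.562 in KO cells (0.180 to 0.944), a difference of -2.48 (interval -2.96 to -2.04). Under ATRA the levels were 5.55 FPKM (4.01 to 7.08) and 0.700 FPKM (0.163 to 1.24), a difference of -1.95 (interval -2.57 to -1.39). The ratio of KO to wild type was 0.0726 under LIF deprivation and 0.126 under ATRA. Prdm5 itself did not separate between the conditions in wild-type cells (-0.42, interval -0.88 to 0.02). The locus lies on chromosome 6 at 65728944 to 65886553 (mm9).

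**Figure D1:**
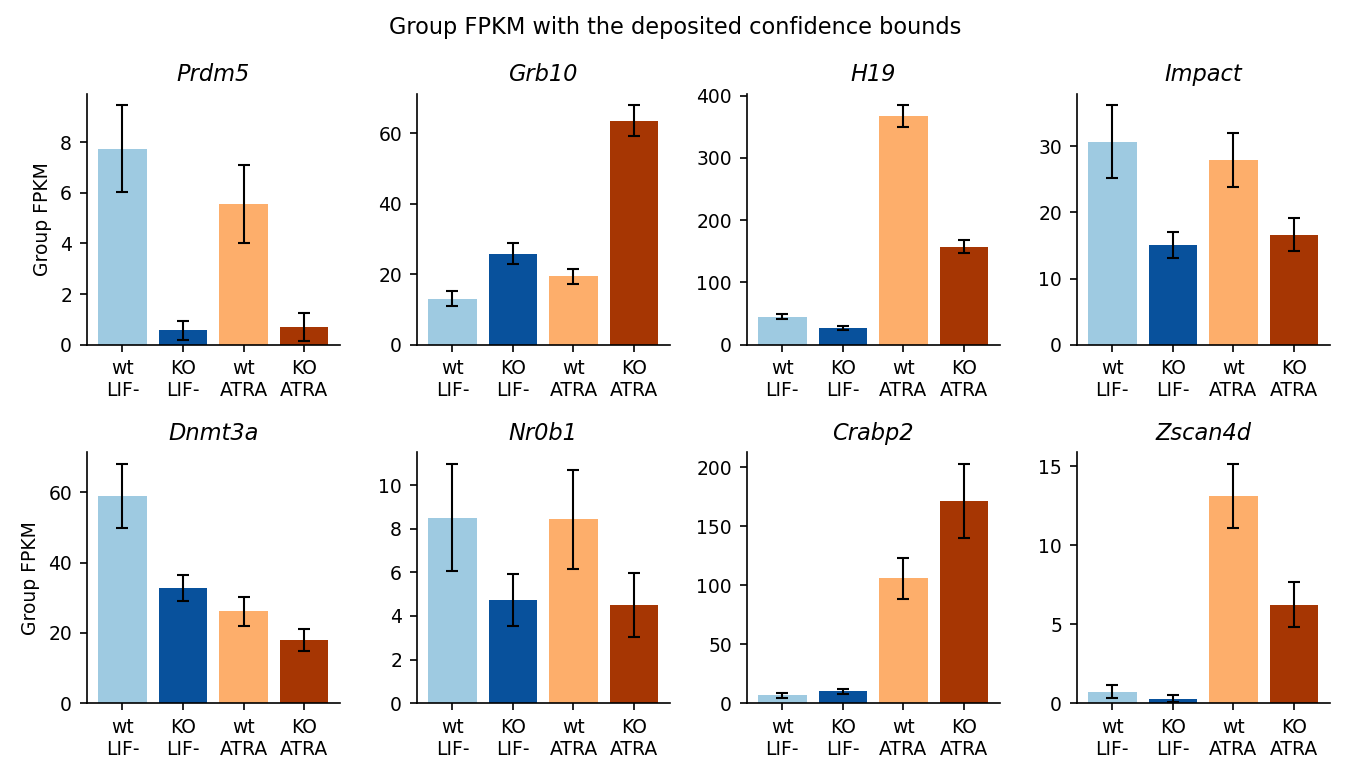
Group FPKM (y axis, linear) of 8 genes in wild-type (wt) and Prdm5 KO cells under LIF deprivation (LIF-) and ATRA; bars are the deposited group values and whiskers the deposited confidence bounds, not replicate error. Prdm5 falls from 7.74 to 0.562 FPKM under LIF deprivation, and Grb10 stands at 25.8 FPKM in KO cells there and at 19.4 against 63.5 FPKM under ATRA.

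Under LIF deprivation, Prdm5 KO cells held less Dnmt3a, Impact, H19 and Nod1 transcript than wild-type cells and more of Grb10. Dnmt3a, a de novo DNA methyltransferase, stood at 59.0 FPKM in wild-type and 32.8 FPKM in KO cells (-0.83, interval -1.09 to -0.55). The imprinted genes Impact, a regulator of translational control, and H19, a non-coding RNA, differed by -0.98 (interval -1.28 to -0.65) and -0.72 (interval -0.93 to -0.52). A further imprinted gene, Grb10, which encodes an adaptor of insulin receptor signalling, moved the other way, to 25.8 FPKM, which was 1.98 times its wild-type level (0.94, interval 0.67 to 1.22). The largest drop after Prdm5 was in Nod1, a sensor of bacterial peptidoglycan, from 2.79 to 0.223 FPKM (-1.63, interval -1.91 to -1.34).

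Of 11319 genes tested in this comparison, 648 were separated, 56 of them higher and 592 lower in KO cells, where 69.7 would be expected by chance from the widths of the intervals alone. Most differences were small: 3 higher and 2 lower genes changed by at least 1 on the log2 scale. Beside Grb10, the largest increases were in Fam25c (1.20), the interferon-inducible gene Ifi27l2a (1.18), the calcium-binding protein S100a1 (1.02), the protease inhibitor Spink3 (0.84) and the small heat shock protein Hspb2 (0.77). Hist2h2bb (0.76), the X-linked homeobox gene Rhox6 (0.76), the ligand Bmp7 (0.75) and the chemokine-like factor Cklf (0.74) came next. Further decreases were in Ggct (-0.81), the slit diaphragm protein nephrin, Nphs1 (-0.78), the smooth muscle actin Acta2 (-0.77) and the thyrotropin-releasing hormone gene Trh (-0.75).

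Naive pluripotency genes lay lower in KO cells under LIF deprivation. The list holds 33 measured members, of which 26 could be tested here and 32 under ATRA. The result here therefore leaves out members that reached 1 FPKM in at least 1 group. Of 26 tested members, 5 were lower, namely the transcription factors Klf4 (-0.83), Sox2 (-0.54) and Tcfcp2l1 (-0.39), the nuclear receptor Nr0b1 (-0.73) and the methylcytosine dioxygenase Tet2 (-0.52). Fbxo15 was higher (0.19), and Pou5f1 stood at 334 FPKM in both genotypes. Tcfcp2l1 and Fbxo15 were singled out after their values were seen. The list's median difference was -0.19, below all of 10000 random lists of genes matched for expression. Nr0b1, Sox2, Trh and the homeobox gene Gbx2 (-0.76) lost their separation after median-ratio or quantile scaling of the groups. Neuronal genes included 3 lower members of 9, Dpysl3 (-0.64) and the intermediate filament genes Nefl (-0.55) and Ina (-0.47), with a list median of -0.15 inside the random range; without the length and GC trends the median was -0.21 and below that range (percentile 0.08). The 6 tested members of the 2-cell-like list, all copies of Zscan4, had a median of -0.39, below the random range (percentile 0.01), but none was separated by itself. Copies that share reads move together, so that percentile overstates how rare the median is.

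Other lists held few separated genes under LIF deprivation, some of them in both directions, though the trophoblast and interferon medians lay above the random range. Of 29 imprinted genes tested, Grb10 was higher, Impact, H19 and the ubiquitin ligase gene Ube3a (-0.43) were lower, and 25 did not separate. Among Wnt targets, the Wnt effector Lef1 (-0.72) and Tcf7 (-0.12) were lower and the repressor Tcf7l1 (0.23) was higher, of 14 tested. Trophoblast markers had 2 higher members of 9, Tcfap2c (0.30) and the keratin Krt8 (0.31), with a list median of 0.13 above the random range (percentile 98.5). No gene of the retinoic acid response (19 tested) or of the Hox clusters (16 tested) separated. Interferon response genes had a median of 0.16 (percentile 99.6) with none of 11 separated.

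Genes of the insulator, cohesin and TFIIIC list, partners of chromatin looping, lay lower in KO cells under LIF deprivation, and replication-dependent histones and ribosomal proteins lay higher. Of 17 insulator, cohesin and TFIIIC genes, 6 were lower, among them the cohesin regulators Pds5a (-0.58) and Pds5b (-0.43), the TFIIIC subunit Gtf3c3 (-0.31) and the cohesin subunit Stag1 (-0.27), and the list median was -0.22 (percentile 0.32). Histones had a median of 0.23 over 51 loci and ribosomal proteins a median of 0.22 over 77, with 2 and 1 members separated. These differences followed transcript length and base composition: genes with transcripts up to 1 kb had a median KO difference of 0.15 and genes over 8 kb one of -0.20. With the trends on length and GC content removed, the medians became -0.03 for the insulator list (percentile 30.0), in which Pds5a and Pds5b stayed lower under both scalings and each trend removal, -0.04 for histones (percentile 12.8) and 0.08 for ribosomal proteins (percentile 94.8).

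The asymmetry between 592 lower and 56 higher genes went with the same trends. The difference correlated across genes with transcript length (Spearman -0.41) and with GC content (0.36); genes are not independent replicates. The higher share was 8.64% as deposited, 30.1% after median-ratio scaling and 45.2% with both trends removed, which left 217 separated genes, 98 higher and 119 lower, 142 of them among the original set. Of the 45 separated genes named for this comparison, 25 kept their call under both scalings and without the trends, among them Prdm5, Nod1, Impact, Klf4, Dnmt3a, H19, Grb10, Lef1 and Dpysl3. Those that lost it without the trends include Fam25c, Spink3, Hspb2, Hist2h2bb, Rhox6, Krt8, Tet2 and Ube3a. The naive pluripotency list kept its position (median -0.20, below all random lists), as did the 2-cell-like list (median -0.38, below all random lists).

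**Figure D2:**
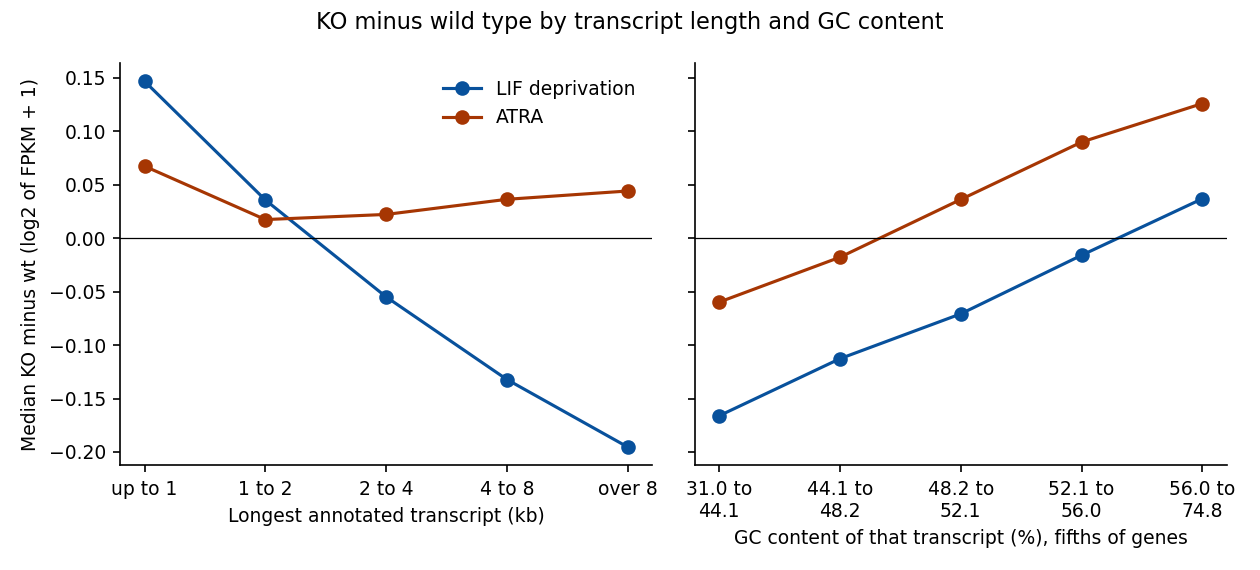
Median KO minus wild-type difference (log2 of FPKM + 1) of genes grouped by the length of their longest annotated transcript (left, kb) and by its GC content (right, percent), under LIF deprivation and ATRA. Under LIF deprivation the median runs from 0.15 in genes up to 1 kb to -0.20 in genes over 8 kb, and with GC content it rises in both conditions.

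Under ATRA, Prdm5 KO cells had less of the Zscan4 copies, of several pluripotency transcripts and of H19, and more of Grb10 and of genes that answer retinoic acid. H19 stood at 367 FPKM in wild-type and 157 FPKM in KO cells (-1.22, interval -1.34 to -1.10), and Grb10 at 19.4 and 63.5 FPKM (1.66, interval 1.49 to 1.84). Tdgf1, the Nodal co-receptor Cripto, fell from 165 to 70.6 FPKM (-1.21, interval -1.37 to -1.06). Crabp2, which carries retinoic acid inside the cell, was at 106 FPKM in wild-type and 171 FPKM in KO cells (0.69, interval 0.33 to 1.04). Zscan4d, a marker of the 2-cell-like state of ES cells, was at 13.1 and 6.24 FPKM (-0.96, interval -1.34 to -0.62).

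In total, 192 of 11858 tested genes were separated, 99 higher and 93 lower in KO cells, against 67.9 expected by chance, and 4 higher and 6 lower genes changed by at least 1 on the log2 scale. By the looser criterion 543 genes were called, fewer than the 592.9 expected by chance. Whether the number exceeds chance therefore depends on the criterion. After median-ratio scaling 193 were separated, 65 higher and 128 lower. Without the length and GC trends 129 were separated, 40 higher and 89 lower, against 65.7 expected by chance. Hist1h4m and Tcf7l1 no longer separated without the GC trend. The remaining large increases were in Fam25c (1.67, from 11.7 to 39.4 FPKM), the synuclein gene Sncg (1.33), the histone gene Hist1h4m (1.01), Ogdhl (0.79), Cercam (0.74), dysferlin, Dysf (0.73), and Rhox9 (0.70). Large decreases were in the cationic amino acid transporter Slc7a3 (-1.12), Apol8 (-1.08), the arginase Arg2 (-1.03), Trh (-0.94) and Ina (-0.85). Sncg lost its separation under each scaling and with either trend removed. Of the 43 separated genes named for this comparison, 28 kept their call under both scalings and without the length and GC trends.

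Retinoic acid response genes lay higher in KO cells under ATRA. Of 19 tested, 4 were higher, Crabp2 (0.69), the transglutaminase Tgm2 (0.58), the retinoic acid hydroxylase Cyp26b1 (0.49) and the Hox cofactor Pbx1 (0.19), none was lower, and the list median was 0.21, above all random lists. Without the length and GC trends the median was 0.20, still above all random lists, and Cyp26b1 no longer separated. The strongest targets did not differ: Stra8 stood at 152 FPKM in both genotypes, Cyp26a1 at 102 and 98.3 FPKM, and Hoxb1 at 33.0 and 34.7 FPKM, and none of 24 Hox genes separated. Trophoblast markers had a median of 0.23 (percentile 99.9) with Esx1 higher (0.34), and extraembryonic endoderm genes one of 0.19 (percentile 99.7) with Cubn (0.39) and Col4a1 (0.19) higher. Without the trends these medians were 0.15 (percentile 99.8) and 0.09 (percentile 95.2), and none of Esx1, Cubn and Col4a1 separated.

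Of the 6 tested Zscan4 copies, 5 were lower in KO cells under ATRA, from Zscan4d (-0.96) and Zscan4e (-0.88) to Zscan4c (-0.75), with a list median of -0.80, below all random lists. The random lists hold genes drawn independently, so for copies that share reads this rank overstates how rare the median is. The summed FPKM of the copies was 71.7 in wild-type and 38.0 in KO cells, a ratio of 0.530. Under LIF deprivation the sums were 4.44 and 1.91, a ratio of 0.431, with bounds that overlapped (from 1.92 in wild-type and up to 3.40 in KO cells). The other members of the 2-cell-like list stayed under 1 FPKM in all groups. Naive pluripotency genes had 3 lower members of 32, Tdgf1 (-1.21), Nr0b1 (-0.78) and the chromatin factor Dppa2 (-0.59), none higher and a median of -0.18, below all random lists. Primed pluripotency genes had 2 lower members of 14, the zinc-finger factor Zic3 (-0.77) and Dnmt3a (-0.51), and a median of -0.05 inside the random range, but of -0.14 without the trends, below it (percentile 0.22). Neuronal genes again included lower members, Ina (-0.85) and the stathmin Stmn2 (-0.47) of 9, with a median of -0.21 (percentile 0.02). Stmn2 no longer separated without the trends, and the median was then -0.24 (percentile 0.01).

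Among 28 imprinted genes tested under ATRA, Grb10, the growth factor receptor gene Igf2r (0.43) and Sfmbt2 (0.47) were higher and H19, Impact (-0.71) and Nnat (-0.37) were lower; Igf2r and Nnat were singled out after their values were seen. Sfmbt2 did not separate after median-ratio or quantile scaling. Germline genes split as well, with Rhox6 (0.57) and Rhox9 (0.70) higher and Ddx4 (-0.41) and Sycp1 (-0.61) lower of 15. Rhox6, Ddx4 and Sycp1 lost their separation without the trends. Replication-dependent histones had a median of 0.31 over 52 loci, above all random lists, and of 0.17 without the trends, also above all random lists. In the ATF4 and unfolded protein response list the asparagine synthetase Asns was lower (-0.32) and the median was -0.10 (percentile 0.82). Ribosomal proteins had a median of 0.05, above all random lists, with Rps28 (0.31) and Rpl37a (0.28) higher, Rpl37a only without scaling, and without the trends the median was -0.01, still above the random range (percentile 99.9). None of 21 insulator, cohesin and TFIIIC genes separated (median 0.00).

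**Figure D3:**
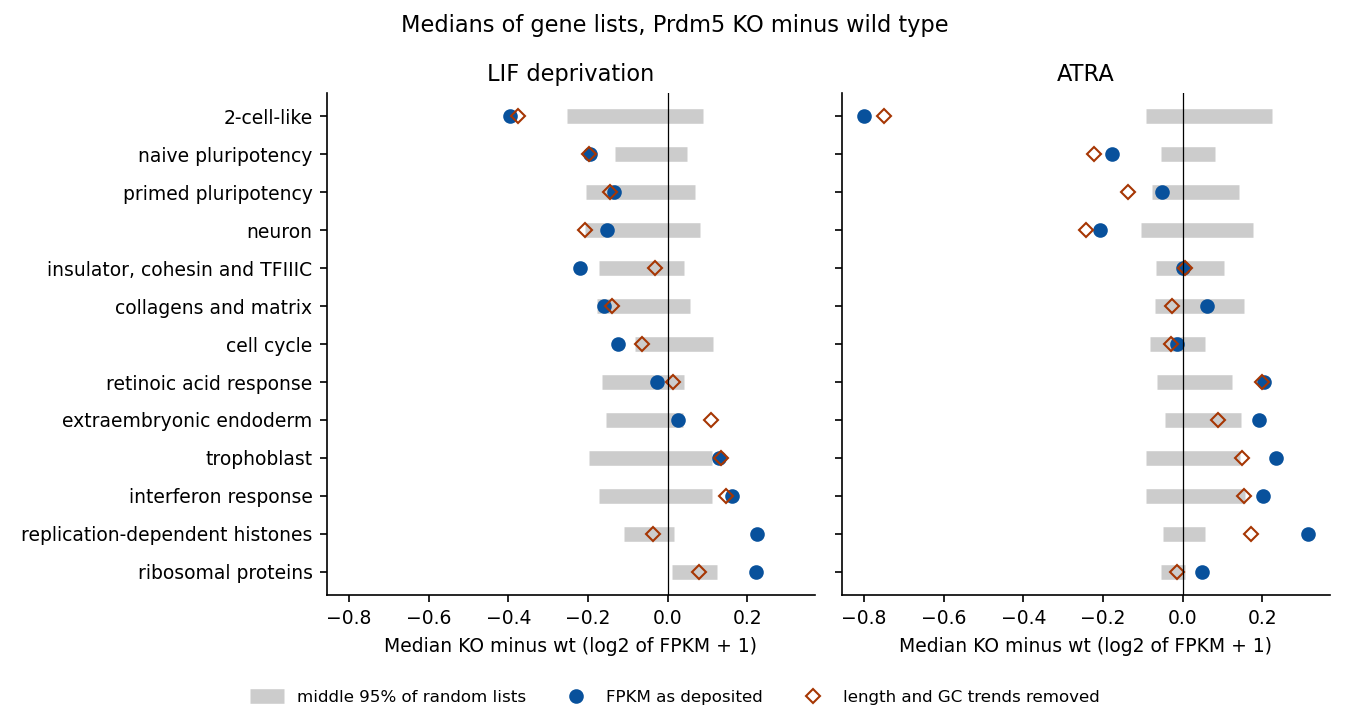
Median KO minus wild-type difference (x axis, log2 of FPKM + 1) of 13 gene lists under LIF deprivation and ATRA, as deposited (circles) and with the length and GC trends removed (diamonds); grey bars span the middle 95% of random lists matched for expression, drawn for the values as deposited. The 2-cell-like list lies at -0.39 and -0.80, and the histone list moves from 0.23 to -0.04 under LIF deprivation when the trends are removed.

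The KO effects in the separate conditions, which share no libraries, overlapped in part. Both set KO against wild-type cells, and the sample titles do not say how many cell lines stand behind each genotype. Any other difference between the lines would be shared as well and cannot be told apart from an effect of Prdm5 loss. Across 11272 genes tested in all groups the differences correlated with Pearson 0.30 and Spearman 0.27, and without Prdm5 Pearson was 0.29; with the GC trend removed they were 0.21 and 0.12. In both conditions 31 genes were lower in KO cells, where 3.08 would be so if the calls were independent, and 7 were higher against 0.37. The shared decreases included Prdm5, Nod1, Impact, Dnmt3a, H19, Nr0b1, Trh, Apol8, Ina, the Ets factor Etv4 (-0.46 and -0.74), the receptor Epha2 (-0.58 and -0.62), the signalling inhibitor Spry2 (-0.40 and -0.60) and the Polycomb subunit Eed (-0.26 and -0.23). Etv4, Epha2, Spry2 and Eed were singled out after their values were seen. After median-ratio scaling 27 were lower and 8 higher in both, against 2.25 and 0.624 if independent, and Epha2, Spry2, Eed, Nr0b1 and Trh no longer separated under LIF deprivation. The shared increases included Grb10, Fam25c, Tcf7l1 and Rhox6, of which Grb10 kept both calls under each scaling and trend removal. Rhox6 lost its call under ATRA after median-ratio scaling and both calls without both trends, Fam25c its call under LIF deprivation without both trends, and Tcf7l1 both calls without the GC trend and that under ATRA without both trends. Another 4 genes were separated in opposite directions as deposited, among them Fads1, Lama5 and Setd5, which were picked after their values were seen. Fads1 and Lama5 lost the call under LIF deprivation under both scalings, Lama5 was higher in both conditions without the length trend, and all 3 lost both calls without both trends, when 1 gene was opposite. With both trends removed, 16 genes were lower and 7 higher in both conditions, against 0.58 and 0.30 if independent. Nod1 was lower in both conditions, by -1.63 and -0.71.

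Whether the KO effect itself differed between the conditions was examined as the difference between the KO minus wild-type differences. For Grb10 it was larger under ATRA by 0.72 (interval 0.39 to 1.05), and for H19 it was more negative under ATRA, by -0.50 (interval -0.73 to -0.26). Sox3, a neural progenitor factor, stood at 3.08 and 4.31 FPKM under LIF deprivation and at 2.51 and 0.919 FPKM under ATRA, a difference of -1.25 (interval -2.12 to -0.44), although neither condition separated by itself as deposited; under ATRA it was lower in KO cells with quantile normalization, without the GC trend and without both trends. The 2-cell-like list differed by a median of -0.48, below all random lists, but with a pseudocount of 0.1 in place of 1 the median was 0.08, inside the random range (percentile 18.4), and as a ratio of summed FPKM the Zscan4 copies were not lower under ATRA (0.530) than under LIF deprivation (0.431), where FPKM near 1 are compressed by the log2 of FPKM + 1. The retinoic acid response list, with many members near or under 1 FPKM under LIF deprivation, differed by 0.28 (percentile 99.9), and by 0.29 (percentile 99.6) with the pseudocount of 0.1. Of these lists 0 and 1 members separated, and with that pseudocount 0 of either. Of 11272 genes, 199 were separated, 191 positive and 8 negative, against 68.3 expected by chance. The whole distribution was shifted by 0.102, and after median-ratio scaling 103 separated, 61 positive and 42 negative. With the length and GC trends removed 42 separated, fewer than the 65.8 expected by chance.

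ATRA changed the wild-type cells far more than the loss of Prdm5 did. Direct retinoic acid targets rose the most: Stra8 from 1.62 to 152 FPKM (5.87, interval 5.46 to 6.38), Cyp26a1, which degrades retinoic acid, from 0.878 to 102 FPKM (5.78, interval 5.39 to 6.27), and the homeobox gene Cdx1 from 0.439 to 50.8 FPKM (5.17, interval 4.76 to 5.65). Hoxb1 rose from 0.0541 to 33.0 FPKM (5.01, interval 4.77 to 5.17), Hoxb2 by 4.81 and Hoxa1 by 4.16. Among the transcripts that fell were Utf1 (-2.38), Sox2 (-1.84), Dppa3 (-1.75) and Pou5f1 (-1.59). Of 11317 genes tested, 3055 were separated, 1642 higher and 1413 lower, against 78.6 expected by chance, and 566 and 408 of them changed by at least 1 on the log2 scale.

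By list, 17 of 19 retinoic acid response genes rose in wild-type cells (median 2.44) and so did 16 of 17 Hox genes (median 2.01), 8 of 9 trophoblast markers (median 1.36; Krt8 2.59 and Esx1 2.52) and all 6 Zscan4 copies (median 2.89; Zscan4f from 1.35 to 20.9 FPKM). Extraembryonic endoderm genes rose in 13 of 20 cases (median 0.94), with Gata6 (3.08), Lama1 (1.94), Foxa2 (1.77) and Col4a1 (1.75) in front. Collagen and matrix genes rose in 9 of 13 cases, led by Bgn (2.44) and Col1a1 (1.74), and fell in 1. Primed pluripotency genes fell in 7 of 10 cases (median -1.10), with Pou3f1 (-2.66), Zic5 (-2.31) and Fgf5 (-2.17) among them. Naive pluripotency genes split, with 9 higher and 11 lower of 27: the T-box factor Tbx3 (2.59) and Klf4 (1.18) rose. Of 9 neuronal genes 6 fell and 2 rose (median -0.91); Crmp1 (-2.18) and Ina (-1.54) fell and Dpysl3 (1.43) rose.

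Further genes with large changes in wild-type cells were Pmp22 (4.15), Zfp703 (4.14) and Crabp2 (3.77), which rose, and the autotaxin gene Enpp2 (-4.33), Hes6 (-3.86), Myb (-3.43), Cbr3 (-2.96), the metallothionein Mt3 (-2.91), Enpp3 (-2.83), Rab25 (-2.83) and Olig1 (-2.70), which fell. A merged locus of Hoxa3 and Hoxa5 rose by 4.26 and one of Pim2 and Slc35a2 fell by 3.06. Imprinted genes rose in 13 of 28 cases and fell in 1 (median 0.58), led by Dlk1 (3.35) and H19 (from 45.0 to 367 FPKM). Wnt targets rose in 8 of 14 cases and fell in 3 (median 1.00), with Dkk1 (1.91) and Sp5 (1.72) among them. Of 14 p53 targets 9 rose and 1 fell (median 0.75), with Perp (2.15) and Plk2 (2.06) highest. Mesoderm and primitive streak genes rose in 5 of 8 cases, with Snai1 (1.72) and Bmp4 (1.65) at the top.

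KO cells answered ATRA with much the same genes. Stra8 rose by 6.48 (interval 6.11 to 6.94), Cyp26a1 by 5.37, Cdx1 by 5.25 and Hoxb1 by 5.06. The homeobox gene Otx2 fell from 31.7 to 0.251 FPKM (-4.71, interval -5.04 to -4.32), Enpp2 by 4.03 and Hes6 by 3.83. Pou5f1 (-1.81), Fgf4 (-1.89) and Utf1 (-2.57) fell as well. Across 11272 genes the ATRA effects in wild-type and KO cells, which share no libraries, correlated with Pearson 0.93 and Spearman 0.89. In both genotypes 1522 genes rose, against 374 if independent, and 984 fell, against 165; 3 moved in opposite directions, namely Akap11, Birc6 and Pcm1. These 3 were singled out after their values were seen, and none moved in opposite directions without the length and GC trends.

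**Figure D4:**
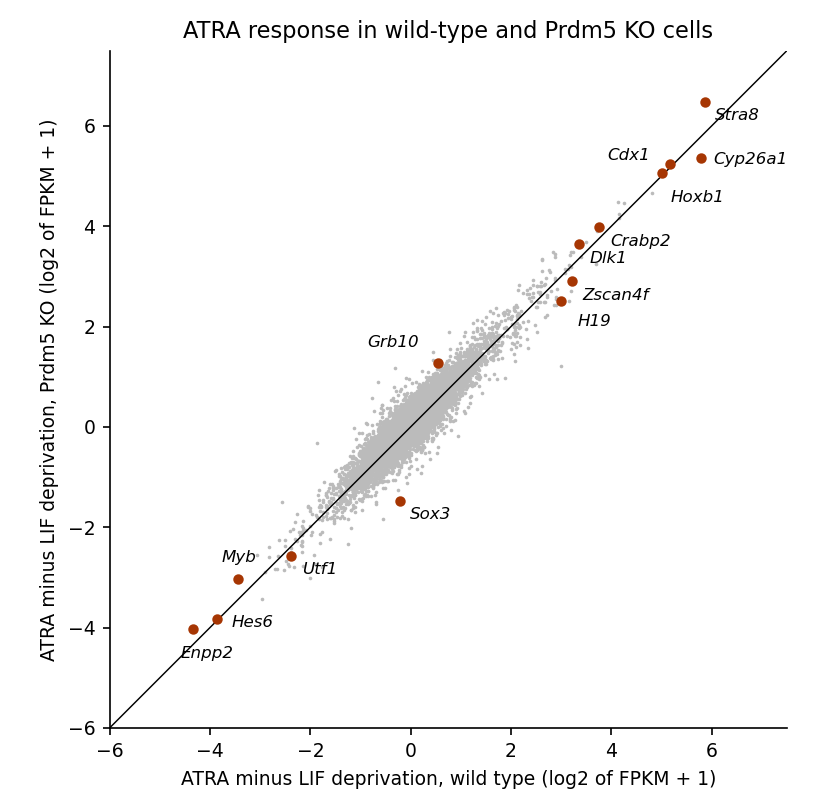
ATRA minus LIF deprivation difference (log2 of FPKM + 1) in wild-type cells (x axis) and in Prdm5 KO cells (y axis), 1 point per gene for 11272 genes, with the line of equal effects and 14 genes named. Most points follow the line (Pearson 0.93 across genes); Grb10 lies above it and Sox3 below it.

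Of 11715 genes tested in KO cells, 4170 were separated, 2724 higher and 1446 lower, against 85.3 expected by chance. All genes together were shifted by 0.118, and after median-ratio scaling, which sets that shift near 0, 4109 genes were separated, 2034 higher and 2075 lower. By list, 17 of 19 retinoic acid response genes (median 2.59), 19 of 19 Hox genes (median 2.13), 9 of 10 trophoblast markers (median 2.12), 15 of 20 extraembryonic endoderm genes (median 1.11), 10 of 14 collagen and matrix genes (median 0.91) and all 6 Zscan4 copies (median 2.47) rose. The trophoblast medians in wild-type and KO cells rest on 9 and 10 tested members. Over the 9 tested in all groups the median interaction was 0.05 (percentile 32.6), and none separated. Primed pluripotency genes fell in 10 of 13 cases (median -1.09) and neuronal genes in 7 of 9 (median -1.02). Of 28 imprinted genes 15 rose and 2 fell (median 0.56), with Dlk1 (3.65) and H19 (from 26.9 to 157 FPKM) first. Acta2 (3.35) and the intermediate filament gene Vim (1.83) rose among fibroblast markers and Thy1 fell (-2.15), and 11 p53 targets of 16 rose, with Cdkn1a (1.45) among them. Of 19 insulator, cohesin and TFIIIC genes 5 rose, including Stag1 (0.49), and with the trends removed 1 rose and 2 fell.

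Markers of other cell types that the cultures could hold were compared as well. Between KO and wild-type cells, fibroblast markers had medians of -0.11 under LIF deprivation (percentile 18.6, and 1.70 without the trends) and -0.05 under ATRA (percentile 11.7), with Acta2 (-0.77) and, only as deposited and not after scaling or without the trends, Cald1 (-0.20) lower under LIF deprivation. Endothelial and blood markers had medians of -0.13 and -0.00 and cardiac and smooth muscle markers -0.06 and -0.05. Between conditions in wild-type cells, fibroblast markers rose in 6 of 11 cases and fell in 2, with Acta2 (2.63) and Tagln (1.79) up and Thy1 (-2.20) down. The endothelial genes Pecam1 (-1.25) and Tek (-0.94) fell. The sex chromosome markers Eif2s3y and Ddx3y, both Y-linked, were present in all 4 groups, Eif2s3y at 22.6 to 30.5 FPKM.

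Around the Prdm5 locus, few genes differed between KO and wild-type cells. Within 5 Mb on each side 6 other genes were tested, of which 1, the chromatin remodeller Smarcad1, was lower under LIF deprivation (-0.37, percentile 96.7 of windows around other genes) and none separated under ATRA. With 6 genes, a call of any 1 gives 16.7%, which is past the 95th percentile of 15.1%. Smarcad1 and Reg2 were chosen after their values were seen. Nod1 and Ggct lie 10.9 Mb from Prdm5 on the same chromosome; both were lower under LIF deprivation, and under ATRA Nod1 was lower (-0.71) while Ggct did not separate (-0.65). Tcf7l1, 6.85 Mb away, was higher in both conditions (0.23 and 0.47), but in neither without the GC trend and only under LIF deprivation without both trends. Within 20 Mb, 9 of 143 genes were separated under LIF deprivation (6.29%, percentile 71.5 of windows of that size around other genes) and 5 of 147 under ATRA (3.40%, percentile 91.9). Reg2, 12.5 Mb from Prdm5, was at 1.69 and 1.54 FPKM in wild-type cells and was listed at 0 in both KO groups.

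**Figure D5:**
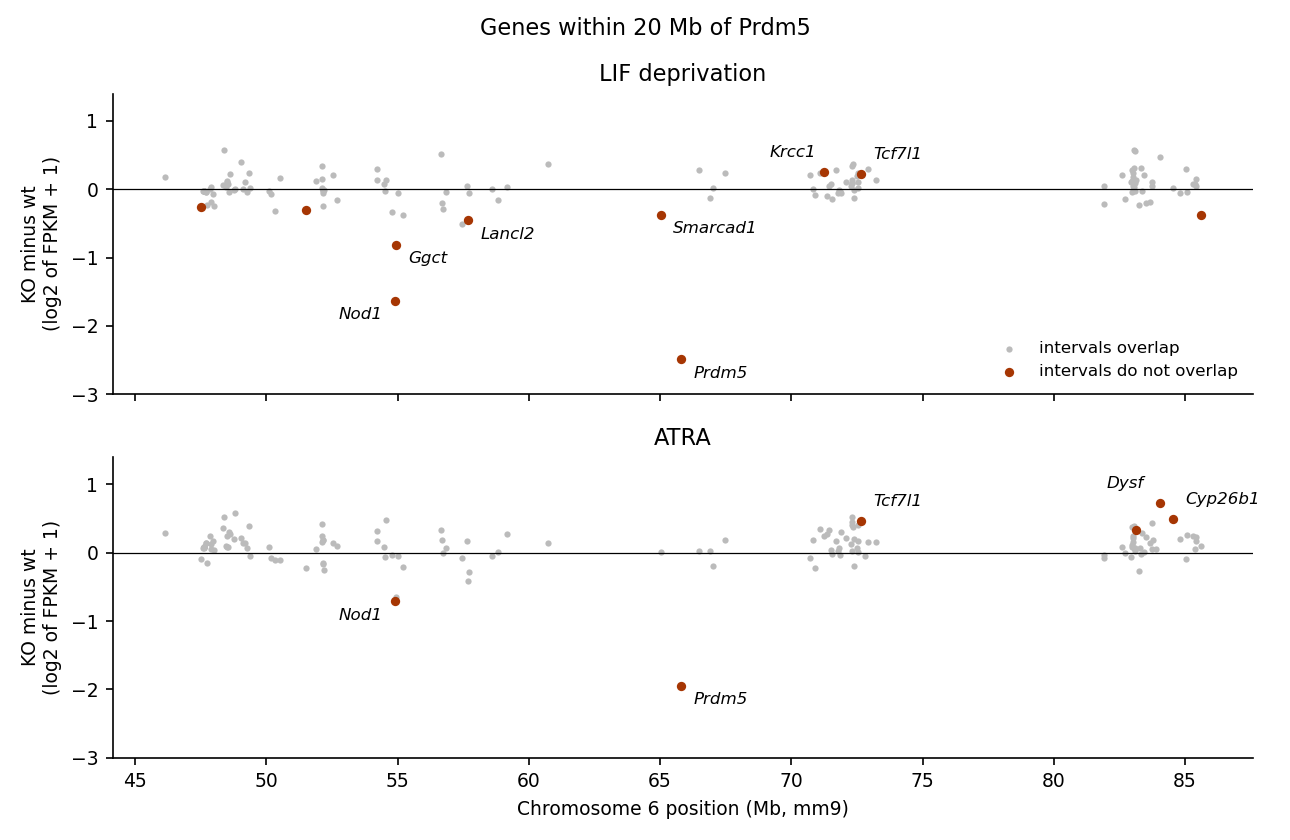
KO minus wild-type difference (y axis, log2 of FPKM + 1) of tested genes within 20 Mb of Prdm5 by position on chromosome 6 (x axis, Mb, mm9), under LIF deprivation (top) and ATRA (bottom); named points are genes whose bounds did not overlap. Prdm5 lies at -2.48 and -1.95, and Nod1 at -1.63 and -0.71.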

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

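Of the tests in this part, those of the asymmetry by scaling, by length and by length with GC content, their limit of 40% and the shuffled control were chosen only after the result, the asymmetry, was seen; the use of both scalings was planned, and the length test was set down before its own value was computed. In 27 of the 210 genes that the text names, the KO effect differed between LIF deprivation and ATRA, by intervals of the differences that did not overlap. Some of these genes were named because they separated, so that share says nothing of genes in general, of which 199 of 11272 separated against 68.3 expected by chance, and 42 against 65.8 without the length and GC trends. The values here are the KO effect under ATRA minus that under LIF deprivation, in log2.

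In 7 genes the difference stayed separated both after median-ratio scaling and without the length and GC trends: Grb10 (0.72), Nod1 (0.92), H19 (-0.50), the ribosomal protein gene Rpl22l1 (-0.38), Sox3 (-1.25), the ubiquitin ligase Uhrf2 (0.50) and the fatty acid desaturase Fads1 (0.53). Grb10 rose more in KO cells under ATRA, and H19 fell more. Nod1 was lower in KO cells in both conditions, and with a pseudocount of 0.1 its difference was larger (1.48) but no longer separated, because its interval widened (-0.26 to 2.93). Rpl22l1 was higher in KO cells under LIF deprivation (0.26) and did not separate under ATRA as deposited (-0.12), though lower there with quantile normalization. Fads1 was lower in KO cells under LIF deprivation (-0.24) and higher under ATRA (0.29) as deposited, but the first call was lost after scaling and both without the trends.

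In 11 further genes the difference stayed separated after scaling but not without the trends: Tet2 (0.59), Dpysl3 (0.67), Pds5b (0.42), Cyp26b1 (0.48), Setd5 (0.52), Mga (0.53), Lama5 (0.46), Iqgap1 (0.44), Sept9 (0.36), Aff4 (0.56) and Tns3 (0.57). In the remaining 9 it stayed separated under neither: Lamb1 (0.47), Ube3a (0.40), Pds5a (0.42), Stag1 (0.37), Loxl2 (0.50), Prdm2 (0.37), Sesn2 (0.38), Col4a1 (0.26) and Nipbl (0.31). Without the trends the values of Pds5a, Ube3a and Nipbl were 0.13, 0.12 and 0.03, so most of their difference went with length and GC content. Cyp26b1 stood at 0.0342 and 0.0419 FPKM under LIF deprivation, where the log2 of FPKM + 1 holds any KO effect near 0, and with a pseudocount of 0.1 it did not separate (0.49, interval -0.36 to 1.48). Of the 27 genes 25 stayed separated with that pseudocount.

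The excess of lower over higher genes in KO cells under LIF deprivation, 592 against 56, was weighed against technical causes. A difference in scaling between the groups is argued against as the whole cause, since after median-ratio scaling 30.1% of the separated genes were higher (binomial interval 25.9% to 34.5%). Removal of the length trend alone left 33.9% (28.4% to 39.8%), its upper end just under the limit of 40%. These intervals take genes as independent trials, which they are not, and hold no spread between libraries. They are therefore likely too narrow, and that for length decides nothing. With the length and GC trends removed together the share was 45.2% (38.4% to 52.0%), so a bias with transcript length and base composition is a candidate explanation for the asymmetry; in 20 runs with length and GC shuffled among genes, which centre the differences alike, it was 27.8% to 28.9%. Quantile normalization gave 25.4%, and removal of the GC trend alone left 134 higher and 201 lower genes. A real loss of long, GC-poor transcripts under LIF deprivation in cells without Prdm5 would leave the same trend, and since no value per library is held, no test here separates it from a technical one. Under ATRA the KO difference correlated across genes with GC content (Spearman 0.37) but hardly with length (0.03). There the share of higher genes went the other way, from 51.6% as deposited to 31.0% without both trends.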

How the results depend on the processing

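The trend removals, the looser criterion and the ratio minimum of 1.5, alone or combined, were tests chosen only after the result was seen; the pseudocount, the filters, the scalings and the larger window were planned. No paired analysis was possible because the file holds 1 value per group, not per replicate. For the same reason a replicate block, leaving out each replicate, limma without trend or with array weights, a fit of 6 samples, camera with estimated correlation and fry were not run, and the authors' own calls and count-based tools could not be used because the file holds neither calls nor counts.

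The loss of Prdm5 transcript stayed separated under each alternative run, from -3.57 to -2.41 under LIF deprivation and from -2.82 to -1.92 under ATRA. The numbers of genes that changed with ATRA stayed within 1.5 times the main number, from 2287 to 4560 in wild-type and from 2903 to 5801 in KO cells. A pseudocount of 0.1, no filter and a minimum FPKM of 5 left all 5 numbers within that margin. Separation between groups is judged on the FPKM bounds, so the pseudocount could change only the interaction, where 193 of the 199 genes were kept. The filters change only which genes are tested. These settings are therefore no check on the calls themselves.

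For KO against wild type under LIF deprivation, 648 separated genes became 382 with quantile normalization, 283 without the length trend, 335 without the GC trend and 217 without both. Of these, 330, 213, 238 and 142 were among the original genes. The looser criterion gave 1373 and a ratio of at least 1.5 gave 110, which differ by construction; that ratio gave 75 with median-ratio scaling and 49 without both trends, where 2 choices change at once. Under ATRA the number stayed within 1.5 times 192 except for the looser criterion (543, against 592.9 expected by chance) and the ratio minimum, with 47 alone, 50 with median-ratio scaling and 42 without both trends. Without both trends alone it was 129, at the edge of that margin, and 91 of these were among the original genes. The balance moved too, from 99 higher and 93 lower to 40 higher and 89 lower. For the interaction, 199 became 103 with median-ratio scaling, 69 with quantile normalization, 51 without the length trend, 98 without the GC trend and 42 without both. The looser criterion gave 648, against 563.6 expected by chance, and the ratio minimum 30 alone, 18 with scaling and 5 without both trends. Apart from the changes made by construction, the cause was not tested.

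Within 20 Mb of Prdm5 the share of separated genes under LIF deprivation was 6.29%, no longer past percentile 95 of windows around other genes. The share separated in both conditions was 1.399%, now just past that percentile. The larger window holds 143 genes and the smaller 6. Rpl22l1 reversed between ATRA and LIF deprivation in wild-type cells, from -0.16 to 0.071 with quantile normalization; the cause was not tested. Each gene was compared with the alternatives only in the comparison for which it was selected. Of these others, 2681 gave the same result, 170 lost separation, 18 moved and 1 gained separation. Of the 2681, 369 came from the pseudocount, 369 from no filter and 327 from the minimum FPKM, settings that by construction leave nearly all calls unchanged. In comparisons not counted there, Lama5 turned from lower to higher under LIF deprivation without the length trend, and Sox3 under ATRA gained separation in 3 settings and Rpl22l1 in 1. For the list medians, 892 comparisons were the same, 105 moved, 56 went outside the random range and 42 came back inside it. The table gives no read counts, so what depth limits can be read only from the bounds, which are widest at low FPKM.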

Other observations

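Of the tests in this part, those on the Zscan4 copies were chosen only after the result was seen, and the share within 20 Mb of Prdm5 in both conditions after the position of Nod1 was seen; the windows of 5 and 20 Mb were planned. Several lists not described so far changed with ATRA. In wild-type cells 6 of 14 ATF4 and unfolded protein response genes fell (median -0.25), led by the serine synthesis gene Psat1 (-1.12), and 4 of 14 fell in KO cells (median -0.29). Hypoxia and glycolysis genes split, with Egln3 (-1.80) lower and the glucose transporter Slc2a1 (1.03) higher among 2 that rose and 4 that fell of 12, and with 3 and 5 of 12 in KO cells. Among immediate early and heat shock genes 4 of 13 rose, with Atf3 (2.44) highest, and Atf3 rose by 2.67 in KO cells. Germline genes rose in 5 of 15 cases (Rhox6 2.04) and fell in 1 (Sycp3 -1.77), and in KO cells in 4 and 1. Interferon response genes fell in 4 of 11 cases, with Bst2 (-1.29) first, and rose in 1, and in KO cells fell in 4 and rose in 3. Ribosomal protein genes fell in 4 of 76 cases (median -0.30) and in KO cells in 7 of 78 (median -0.49). Among Prdm genes Mecom (0.98) rose and Prdm1 (-0.92) fell in wild-type cells. Neural progenitor genes included higher Gbx2 (1.07) and Nes (1.02) and lower Olig2 (-2.23). Cell cycle genes rose in 1 and fell in 3 of 22 cases, among them Mcm7 (-0.65). Of 51 replication-dependent histone loci 1 rose and 1 fell. Of 17 insulator, cohesin and TFIIIC genes 3 fell in wild-type cells, Gtf3c3 (-0.49), Pds5a (-0.45) and Nipbl.

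Between KO and wild-type cells many of the further lists lay inside the random range. Under LIF deprivation and ATRA the medians were -0.10 and 0.10 for the Prdm family (Prdm2 lower under LIF deprivation, -0.25), 0.10 and 0.16 for mesoderm and primitive streak (percentiles 98.3 and 88.6; 0.08, percentile 87.6, without the trends under LIF deprivation), -0.15 and -0.17 for neural progenitor (percentiles 11.5 and 0.49), -0.14 and -0.05 for primed pluripotency, and 0.03 and 0.19 for extraembryonic endoderm. They were -0.16 and 0.06 for collagens and matrix (Loxl2 -0.34 under LIF deprivation), -0.03 and 0.05 for p53 targets (Sesn2 -0.30 under LIF deprivation, Zmat3 0.16 under ATRA), and -0.08 and 0.01 for Wnt targets. Those of p53 targets under LIF deprivation and of Wnt targets under ATRA change sign with scaling. Further medians were -0.13 and -0.01 for the cell cycle (percentiles 0.38 and 51.0; -0.06, percentile 3.60, without the trends under LIF deprivation), -0.13 and -0.09 for immediate early and heat shock genes (percentiles 10.1 and 1.77), -0.13 for ATF4 and unfolded protein response genes under LIF deprivation, -0.07 and -0.05 for hypoxia and glycolysis (the former changes sign with median-ratio scaling), 0.20 for the interferon response under ATRA (percentile 99.6) and -0.02 and -0.04 for germline genes. Hox genes had medians of -0.02 and 0.09, and the sex chromosome markers -0.18 and 0.25, with Ddx3y lower under LIF deprivation as deposited (-0.36) and not separated under either scaling. Without the length and GC trends several medians lay outside the random range: under LIF deprivation those for primed pluripotency (-0.14, percentile 0.59), collagens and matrix (-0.14, percentile 0.41), immediate early and heat shock genes (-0.15, percentile 0.18), ATF4 and unfolded protein response genes (-0.09, percentile 2.32), the interferon response (0.15, percentile 98.4) and extraembryonic endoderm (0.11, percentile 99.4), and under ATRA those for neural progenitor (-0.20, percentile 0.20), immediate early and heat shock genes (-0.12, percentile 1.56), the interferon response (0.15, percentile 99.6), sex chromosome markers (0.36, percentile 99.8), ATF4 and unfolded protein response genes (-0.17, percentile 0.02) and hypoxia and glycolysis (-0.11, percentile 1.90). The median changed sign without the trends for germline genes (0.03), collagens and matrix (-0.03) and Wnt targets (-0.07) under ATRA and for the sex chromosome markers (0.01) under LIF deprivation. Of 23 entries for clustered protocadherins 1 was tested, a locus that merges the alpha and gamma genes, which did not separate between genotypes (-0.06 and 0.21) and rose with ATRA in KO cells (0.43), but not after scaling. The mitochondrial list has no entries in the table. Polr2a, which encodes the largest subunit of RNA polymerase II, was listed at 0 in both wild-type groups and at 1.90 and 0.474 FPKM in the KO groups. A listing at 0 is not taken here as absence of the transcript or as a difference between genotypes.

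The lower level of the 2-cell-like list in KO cells under ATRA rests on 6 near-identical Zscan4 copies. Sharing of reads between the copies does not change their sum, and the summed FPKM of KO cells was 0.530 of that of wild-type cells, with bounds that did not overlap (28.6 to 47.4 against 57.0 to 86.3), which argues against it. The retinoic acid response list gave no sign of a generally weaker response to ATRA. Its median difference was 0.21, above all random lists, with 4 of 19 members higher and none lower. That median was already known when this test was chosen. The list does not speak to a weaker response of the Zscan4 copies themselves. A smaller number of 2-cell-like cells in the KO culture is possible as well. Of the 6 copies, 0 had an interval that left out the list median, as fewer such cells would give, but copies that share reads move together in any case. Fewer cells and less transcript per cell therefore cannot be told apart here.

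Genes near Prdm5 were examined by plan. The share called the same way in both conditions within 20 Mb was added after Nod1 was seen to lie on the same chromosome. Nod1 was lower in both conditions, and Tcf7l1, also on that chromosome, was higher in both. Trh, lower in both as deposited (-0.75 and -0.94), lies on that chromosome too, at 92192055 to 92194653, outside the window of 20 Mb. For chance placement, the share of genes within 20 Mb called the same way in both conditions, 2 of 143, stood at percentile 95.3 of windows around other genes. Those windows include ones near Prdm5 that overlap its own. That share counts Nod1, which drew attention to the region, and Tcf7l1, which lost both calls without the GC trend and the call under ATRA without both trends, and its binomial interval (0.170% to 4.96%) is wide, so the percentile decides nothing, and chance and a local effect cannot be told apart. For an effect spreading from the Prdm5 locus, 0 of 6 genes within 5 Mb were called in both conditions, and with 6 genes a share of up to 45.9% is not ruled out. A variant carried along with the KO allele, such as flanking DNA of another strain, was not tested, because the table holds no sequence.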
